A study of Mus musculus with 12 samples.

How the data were processed

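Bulk RNA was sequenced from the prefrontal cortex and the striatum of C57BL/6J mice at postnatal day 24. The series describes a postnatal model of attention-deficit/hyperactivity disorder made with 6-hydroxydopamine (6-OHDA), a toxin that kills dopamine neurons, beside control mice. The labels gave 4 groups of 3 libraries, lesioned and control in each region, and 12 libraries in all. Per the labels' protocols, mRNA was purified from 500 ng of total RNA with an RNA integrity number of at least 8.9, made into stranded libraries and read as 101 bp pairs. The dose, route and day of the 6-OHDA treatment are not given in the sources used here. No label says that the 3 libraries of a group came from separate animals or that a number marks the same animal in both regions, so the p-values measure the spread between these libraries.

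The authors deposited read counts per gene symbol in 1 table, which holds 21872 symbols and no normalised value. Alignment to mm10 with STAR 2.7.1a and counting with featureCounts are named in the submitters' processing notes. The annotation, the strand setting and the treatment of reads that match several genes are not given in the sources used here, so the counts of overlapping genes, antisense partners and close paralogs such as the haemoglobin and linker histone genes are uncertain. Total counts ranged from 15078631 to 20925452 per library, so that the floor of 3 counts lay between 0.143 and 0.199 CPM (counts scaled to the library total). Such floors cover counting error only. In all, 3732 symbols were at 0 in every library, among them the 13 mitochondrially encoded genes, which are listed at 0.

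Part of the deposited table does not hold raw read counts. Among the 18140 genes above 0 in any library, 1830 hold only multiples of 11, with 11 as their lowest value above 0. These 1830 are exactly the genes at 0 in the lesioned prefrontal library with the number 1. Among genes above 0 in at least 4 libraries, 630 hold only multiples of 11, against 4 for multiples of 2 and 0 for multiples of 3. These genes carry 0.144% of all counts, and the step that made them is not given in the sources used here. They were left out of every main test after the data had been examined, although the tests had been planned on the whole table, since a count model assumes read counts. The choice removes genes by their zeros in 1 library and therefore removes few strongly expressed genes: 788 of them passed the filter as deposited and 46 after division by 11. Among them were 13 members of the gene lists, including Il6, Tnf, Ccl2, En1 and Foxa2. The tests were repeated with these genes kept and with their values divided by 11.

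Counts were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16, after filterByExpr on the 4 groups, which left 14545 genes, and TMM normalisation. All 12 libraries entered 1 fit with group as the only term and 8 residual degrees of freedom. The contrasts were lesioned against control in prefrontal cortex, the same in striatum, the difference between these effects, and control striatum against control prefrontal cortex. P-values were two-sided, adjusted by Benjamini and Hochberg, with calls at an adjusted p below 0.05. Fold changes are lesioned over control unless another direction is named. Standard errors (SE) of log2 fold changes are the absolute fold change over the root of the F statistic. Since the spread differed between regions, the same test on the 6 libraries compared is printed beside the main counts.

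Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, beside camera with an estimated correlation and fry, with p-values adjusted over lists. Of 43 lists, which name 915 genes, 41 had at least 5 tested members. The mitochondrially encoded genes and the sex-linked transcripts had fewer and were not tested. The design, the gene lists, the alternatives named first in the next paragraph and the rule for naming genes were fixed before the data were examined. For each lesion contrast the rule takes the 12 called genes with the largest change in each direction among those above 1 CPM on average whose libraries do not overlap between groups and that have a regular gene name. It adds the 8 largest for the difference between regions, up to 4 members with the smallest p of each list, and 10 genes of the dopamine system whatever their values. For the regions in controls it takes the 8 largest in each direction above 10 CPM. A list of hypothalamic markers was written later, after transcripts of the hypothalamus had been seen in striatal libraries. The results of 2 genes that the rule takes are not reported here, although counts of genes and lists include them.

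The alternatives chosen before the data were examined were RLE and upper-quartile factors, mitochondrial genes left out, DESeq2 1.42.0, limma-voom, no filter on low counts, at least 1 CPM in 3 libraries, the compared libraries alone, the replicate number as a block, the animal number shared by both regions as a block, 1 surrogate variable from sva 3.50.0, an adjusted p below 0.1, a minimum log2 fold change of 0.3, an estimated correlation or fry for the lists, and leaving out each library. Alternatives chosen after seeing the data were a correction of each library for GC content and transcript length, the fit without the 2 striatal libraries in doubt, limma-voom with quality weights, DESeq2 and limma-voom on the compared libraries, the other treatments of the multiples of 11, leaving out each library with DESeq2 or with edgeR on 1 region, and the list medians without each library of a region. Lengths, GC content and coordinates came from GENCODE M21 (GRCm38), in which 21472 of the symbols were found. Positions are 1-based.

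The scripts were tested on simulated counts drawn from the means and spreads of these libraries. With all 12 libraries in the fit, 53.7% of genes changed 1.5-fold and 83.3% of those changed 2-fold were called in prefrontal cortex with 1 false call, and 64.2% and 87.9% in striatum with 69 false calls. With the 6 libraries of a region, these shares were 81.5% and 89.2% in prefrontal cortex with 11 false calls, and 18.5% and 68.2% in striatum with 4. With no simulated effect and all 12 libraries, 0 genes were called in prefrontal cortex and 18 in striatum. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The co-expression modules that the series mentions were not analysed here.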

Results

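Gene expression was measured by mRNA sequencing in prefrontal cortex and striatum of mice at postnatal day 24, in 3 lesioned (6-OHDA) and 3 control libraries of each region. Both regions receive input from dopamine neurons, a target of this toxin. Total counts lay between 15078631 and 20925452 per library, and 14545 genes were tested. The spread between replicates differed by region: the biological coefficient of variation was 5.8% in prefrontal cortex and 14.9% in striatum when each was fitted alone, and 11.3% in the fit of all 12 libraries.

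Control striatum and control prefrontal cortex differed in 6243 genes, of which 3149 were higher in striatum and 3094 lower. Among the genes higher in striatum were Dlk1 with a log2 fold change of 6.22 (SE 0.48, adjusted p = 1.85e-06), the orphan receptor Gpr101 with 6.15 (SE 0.41) and the prolactin receptor Prlr with 5.74 (SE 0.71). Among those lower in striatum were Myl4 with a log2 fold change of -5.27 (SE 0.35) and Hkdc1 with -5.29 (SE 0.22). The mean log2 CPM of striatal projection neuron markers was 6.92 ± 0.34 (SD, n = 3) in control striatum and 5.40 ± 0.46 in control prefrontal cortex. Cortical excitatory neuron markers had a mean of 6.41 ± 0.05 in control prefrontal cortex and 3.53 ± 1.36 in control striatum, where the single libraries lay at 2.30, 4.99 and 3.30. Hypothalamic markers, a list written after such transcripts were seen, had means of 4.11, 2.98 and 4.07 in the 3 control striatal libraries. Their means were 2.43, 3.91 and 3.98 in the 3 lesioned ones, against 0.79 to 1.13 in the 6 prefrontal libraries. The lesioned library at 2.43 had 655 counts of Dlk1, 550 of Gpr101 and 77 of Prlr. The other lesioned striatal libraries had 1930 and 1847 of Dlk1, 1322 and 1030 of Gpr101, and 644 and 477 of Prlr. Prlr is also on the list of choroid plexus and ependymal markers. Whether these 3 genes come from striatal cells or from bordering tissue was not tested.

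In prefrontal cortex, 30 genes changed after the lesion, 11 higher and 19 lower, with a median absolute log2 fold change of 0.54. Among the calls with the smallest p was Cbs, which encodes the transsulfuration enzyme cystathionine beta-synthase and lies on chromosome 17 at 31608894 to 31637238. It fell from 40.1 ± 2.75 CPM to 20.6 ± 2.23 (SD, n = 3 each; log2 fold change -0.97, SE 0.11, adjusted p = 0.0143). The spermine oxidase Smox, on chromosome 2 at 131491496 to 131525922, fell from 44.8 ± 1.59 to 29.5 ± 1.98 CPM (-0.60, SE 0.07, adjusted p = 0.0143). Sat1, which acetylates spermidine and spermine and was picked out after its values were seen, fell as well (-0.53, SE 0.08). The secreted phospholipase Pla2g3 fell by 1.07 on the log2 scale (SE 0.16) and the transcription factor Sox21 by 0.71 (SE 0.11). Other falls were those of the Notch-regulated protein Nrarp (-0.66, SE 0.10), the monocarboxylate transporter Slc16a1 (-0.60, SE 0.10), the fatty acid elongase Elovl2 (-0.57, SE 0.09) and the protease Htra1 (-0.55, SE 0.09). With a correction for GC content and transcript length, Slc16a1 (-0.60, SE 0.11) and Elovl2 (-0.57, SE 0.10) were not called (adjusted p = 0.0628 for each). The other falls named here kept their calls.

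Among the genes that rose in prefrontal cortex, the linker histone genes H1f4 (2.27, SE 0.32, adjusted p = 0.0303) and H1f2 (1.19, SE 0.20, adjusted p = 0.0356) had the largest fold changes. H1f2 went from 12.5 ± 3.31 to 28.5 ± 3.41 CPM. H1f4 was low, with 6, 6 and 8 counts in the control libraries and 36, 34 and 32 in the lesioned ones. The histone methyltransferase gene Kmt2a, on chromosome 9 at 44803355 to 44881296, rose from 153.7 ± 2.76 to 216.4 ± 6.30 CPM (0.49, SE 0.06, adjusted p = 0.0206), and its relative Kmt2c rose by 0.33 (SE 0.05). Utp14b (0.97, SE 0.17), the pseudokinase gene Trib1 (0.68, SE 0.11), Lgi4 (0.43, SE 0.06), Vps13c (0.41, SE 0.07) and the ubiquitin ligase gene Mycbp2 (0.39, SE 0.06) also rose. With a correction for GC content and transcript length Kmt2a was at 0.30 (SE 0.05), Kmt2c at 0.16 (SE 0.05), Mycbp2 at 0.21 (SE 0.05) and Vps13c at 0.28 (SE 0.07), and none of these 4 was called. Utp14b (0.92, SE 0.17) and Trib1 (0.65, SE 0.11) moved less and were not called either, while Lgi4 (0.41, SE 0.05) kept its call. In all 30 genes the 3 lesioned libraries lay apart from the 3 controls, against 24.9% of all tested genes and 10% by chance.

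The 6 prefrontal libraries fitted alone gave 803 genes, 484 higher and 319 lower, with a median absolute log2 fold change of 0.29; they include the 30. With a correction for GC content and transcript length, 16 genes were called, 2 higher and 14 lower, against 11 and 19 without it. Of these 16 genes, 14 were among the 30. Genes without an annotated length, H1f2 and H1f4 among them, were not tested with this correction, so they could not be called. Without any 1 of the 6 prefrontal libraries edgeR called 0 genes in the fit of the 11 others. Then 1163 to 1391 genes had an unadjusted p below 0.05, and DESeq2 called 53 to 148. With edgeR on the prefrontal libraries alone, leaving out each of them gave 195 to 1010 genes. The count of 0 therefore holds for the fit with striatal libraries and not for prefrontal libraries alone. The fit of all 12 takes a biological coefficient of variation of 11.3%, where prefrontal cortex alone has 5.8%. In simulated counts it called 53.7% of genes changed 1.5-fold in prefrontal cortex, against 81.5% with the 6 libraries.

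By list, camera gave 12 lists in prefrontal cortex, 6 higher and 6 lower. With an estimated correlation 0 lists passed (smallest adjusted p = 0.598; 2 lists at an unadjusted p below 0.05), as did 0 with fry (6 lists unadjusted). Astrocyte markers went lower (adjusted p = 5.01e-05; adjusted p = 0.598 with an estimated correlation). Of 17 members 0 were called over all genes tested, and 5 lower and 1 higher when adjusted over the list alone. In the prefrontal libraries alone 10 of these members fell and 1 rose, among those that fell Fgfr3 (-0.43, SE 0.06, adjusted p = 0.0014 in that fit), Sox9 (-0.56, SE 0.10, 0.0063), the water channel gene Aqp4 (-0.35, SE 0.07, 0.0105) and Acsbg1 (-0.29, SE 0.05, 0.0045). Oligodendrocyte precursor and committed cell markers were lower (adjusted p = 2.83e-04; adjusted p = 0.650 with an estimated correlation), with log2 fold changes of -0.60 for Enpp6 and -0.33 for Olig2 and 0 of 17 members called by either adjustment. Nuclear-encoded respiratory chain genes were lower by a median of -0.09 (adjusted p = 2.04e-06; adjusted p = 0.650 with an estimated correlation), with 0 of 61 called by either adjustment and values of -0.25 for Atp5e and -0.20 for Atp5g1. Without control library 3 the respiratory chain median was -0.05 and Enpp6 was at -0.39. Immature neuron and proliferation markers had a median of -0.25 (adjusted p = 0.0060; adjusted p = 0.726 with an estimated correlation) with 0 of 19 called by either adjustment; Sox4 was at -0.41 (SE 0.11) and Tubb3 at -0.32 (SE 0.10). Heat shock and unfolded protein genes were lower (median -0.05, adjusted p = 0.0197; adjusted p = 0.752 with an estimated correlation). Of 22 members, the disulfide isomerase gene Pdia4 fell (-0.38, SE 0.07, adjusted p = 0.0456), and 2 were lower when adjusted over the list alone. The heat shock list did not pass without lesioned library 1 (adjusted p = 0.0637) or control library 2 (median -0.03, adjusted p = 0.0595).

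Interferon-response genes were higher in prefrontal cortex (median 0.28, adjusted p = 1.11e-04; adjusted p = 0.650 with an estimated correlation). Of their 23 members 22 had a fold change above 0 and 0 were called, 2 when adjusted over the list alone; Ifit3b was at 0.99 (SE 0.25) and Ifit3 at 0.85 (SE 0.21). Potassium channels (median 0.12, adjusted p = 0.0090; adjusted p = 0.598 with an estimated correlation) and sodium and calcium channels (median 0.13, adjusted p = 0.0060; adjusted p = 0.726 with an estimated correlation) were higher with 0 of 44 and 0 of 29 members called, and 0 and 1 higher when adjusted over the list alone. In the prefrontal libraries alone 11 and 8 of these members rose and 2 and 0 fell, those that rose including Kcnh5 (0.50, SE 0.08, adjusted p = 0.0032 in that fit) and Cacna1b (0.27, SE 0.05, 0.0047). Immediate early genes were higher (median 0.23, adjusted p = 0.0414; adjusted p = 0.752 with an estimated correlation) with 0 of 24 called and 2 when adjusted over the list alone; Arc was at 0.75 (SE 0.30), Dusp1 at 0.72 (SE 0.19) and Fos at 0.25 (SE 0.22, adjusted p = 0.761). Genes with reported or candidate links to attention-deficit/hyperactivity disorder were higher (median 0.13, adjusted p = 0.0189; adjusted p = 0.650 with an estimated correlation), with 0 of 26 called by either adjustment and values of 0.26 for Pcdh7 and 0.26 for Sorcs3. Striatal projection neuron markers were lower (median -0.39, adjusted p = 0.0469; adjusted p = 0.752 with an estimated correlation) with 0 of 15 called by either adjustment. The single libraries overlapped, with list means of 5.32, 4.77 and 5.14 log2 CPM after the lesion and 4.97, 5.34 and 5.89 in controls. Their median was -0.11 without control library 3 (adjusted p = 0.485), -0.20 without lesioned library 2 (adjusted p = 0.240), -0.47 without control library 2 (adjusted p = 0.0509) and -0.63 without control library 1. Immediate early genes did not pass without lesioned library 2 (adjusted p = 0.0998) or control library 1 (adjusted p = 0.230). Disorder genes did not pass without lesioned library 2 (adjusted p = 0.0817) or control library 1 (median 0.06, adjusted p = 0.230).

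After the correction for GC content and transcript length, 5 lists of prefrontal cortex no longer passed camera. Their medians and quartiles were 0.12 (0.03 to 0.25) before and 0.09 (-0.01 to 0.16) after for potassium channels (adjusted p = 0.304). For sodium and calcium channels they were 0.13 (0.03 to 0.25) before and 0.08 (-0.02 to 0.17) after (adjusted p = 0.467), and for heat shock genes -0.05 (-0.14 to 0.04) before and -0.03 (-0.13 to 0.04) after (adjusted p = 0.232). Respiratory chain genes had -0.09 (-0.13 to -0.03) before and -0.07 (-0.11 to 0.00) after (adjusted p = 0.101), and disorder genes 0.13 (0.03 to 0.23) before and 0.12 (-0.05 to 0.17) after (adjusted p = 0.317). Why these calls ended was not tested. Of 3 lists that passed with the correction and not before, extracellular matrix genes were lower (-0.07 (-0.23 to 0.04) before and -0.15 (-0.27 to 0.00) after, adjusted p = 4.07e-04). Postsynaptic scaffolds were lower too (-0.04 (-0.13 to 0.04) before and -0.07 (-0.18 to 0.00) after, adjusted p = 0.0112). Choroid plexus and ependymal markers were higher (0.27 (-0.07 to 0.59) before and 0.32 (0.00 to 0.64) after, adjusted p = 0.0226). Before the correction their list means overlapped, at -0.119, 0.503 and -0.283 log2 CPM after the lesion and -0.375, -0.524 and -0.177 in controls. Without lesioned library 2 the uncorrected value of their member Ttr was 0.486 in place of 5.865.

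In striatum, 1040 genes were called in the fit of all 12 libraries, 603 higher and 437 lower. Their median absolute log2 fold change was 0.59. The 6 striatal libraries fitted alone gave 4 genes, 1 higher and 3 lower. The fit of all 12 takes a biological coefficient of variation of 11.3%, where striatum alone has 14.9%. In simulated counts it made 69 false calls in striatum, against 4 with the 6 libraries. The share of false calls was above 0.05, so its adjusted p-values for single striatal genes are too small. Impg1 rose from 0.70 ± 0.43 to 4.56 ± 0.17 CPM (SD, n = 3; log2 fold change 2.71, SE 0.46) and the thrombospondin gene Thbs4 from 4.67 ± 0.44 to 17.9 ± 5.34 (1.94, SE 0.26). The activin receptor gene Acvr1c (1.94, SE 0.30) and the integrin gene Itga5 (1.79, SE 0.37) rose too. Among the largest falls were those of genes near 0 counts in lesioned striatum, whose fitted fold changes are no bounds. Ttr, the main product of the choroid plexus, had 83, 33996 and 632 counts in the control libraries and 1, 30 and 16 in the lesioned ones. It was not called without control library 2 (adjusted p = 0.127). Kcnj13 had 6, 248 and 19 counts in controls and was listed at 0 in the 3 lesioned libraries. The E-cadherin gene Cdh1 had a mean of 1.93 ± 1.05 CPM in controls and 0.06 ± 0.06 after the lesion.

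The projection neurons of the striatum carry dopamine receptors and their signalling proteins, and these gene groups were higher in lesioned striatum. Of 15 tested striatal projection neuron markers 10 rose, all 15 were higher when adjusted over the list alone, and their median log2 fold change was 1.29 (adjusted p = 1.88e-08; adjusted p = 0.496 with an estimated correlation). The phosphodiesterase gene Pde10a, on chromosome 17 at 8525372 to 8986648, rose from 482.9 ± 90.3 to 1522 ± 819 CPM (1.66, SE 0.35, adjusted p = 0.0243). The sodium channel subunit gene Scn4b rose from 375.5 ± 135.0 to 1369 ± 850 (1.87, SE 0.43), the transcription factor gene Foxp1 from 100.8 ± 13.4 to 243.3 ± 99.5 (1.27, SE 0.22) and Ido1 from 3.42 ± 1.52 to 12.2 ± 6.78 (1.82, SE 0.42). Of 21 dopamine receptor and signalling genes 8 rose and 0 fell, 17 and 1 when adjusted over the list alone (median 0.90, adjusted p = 1.07e-06; adjusted p = 0.496 with an estimated correlation). These 8 include Pde10a, Pde1b (1.31, SE 0.27) and Arpp19 (1.34, SE 0.21). Without lesioned library 1 and control library 2 the projection neuron median was 0.70 with 4 members called, and without control library 2 it was 1.11 with 1 called. For dopamine receptor and signalling genes the median was 0.54 without lesioned library 1, with 4 called, and 0.40 without both, with 5 called. Scn4b was at 1.24 without lesioned library 1 (adjusted p = 0.0732). Without both libraries Pde10a was at 0.99, Foxp1 at 0.81, Ido1 at 1.06 (adjusted p = 0.0865), Pde1b at 0.74 and Arpp19 at 0.86.

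Of 8 markers of D2 projection neurons, which form the indirect pathway, 2 rose. The count was 6 when adjusted over the list alone (median 1.245, adjusted p = 0.0025; adjusted p = 0.496 with an estimated correlation). The enkephalin precursor gene Penk, on chromosome 4 at 4133531 to 4138819, rose 2.38-fold, from 434.8 ± 110.0 to 1035 ± 289 CPM (SE of the log2 fold change 0.30, adjusted p = 0.0332), and the orphan receptor gene Gpr52 rose by 1.24 (SE 0.28). Of 9 markers of D1 projection neurons, which form the direct pathway, 1 rose, the muscarinic receptor gene Chrm4 (1.001, SE 0.21). The count was 2 when adjusted over the list alone (median 0.47, adjusted p = 0.0634). With lesioned library 1 left out, the D2 median was 0.77 and the D1 median 0.28, with Gpr52 at 0.76 and Chrm4 at 0.64. Without control library 2 as well the medians were 0.58 (adjusted p = 0.0528) and 0.12. The D1 list passed without lesioned library 2 (adjusted p = 0.0181) or control library 1 (adjusted p = 0.0341). In the same libraries, cell type markers differed by list. The list mean of projection neuron markers was 8.86, 7.55 and 8.05 log2 CPM in the 3 lesioned libraries and 7.03, 6.54 and 7.20 in controls. The mean of cortical excitatory neuron markers was 3.80, 3.72 and 3.21 against 2.30, 4.99 and 3.30. The mean of meningeal and fibroblast markers was 1.09, 1.46 and 1.52 against 2.65, 3.33 and 2.74. The plot of marker lists in striatal libraries shows these values.

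**Figure D1:**
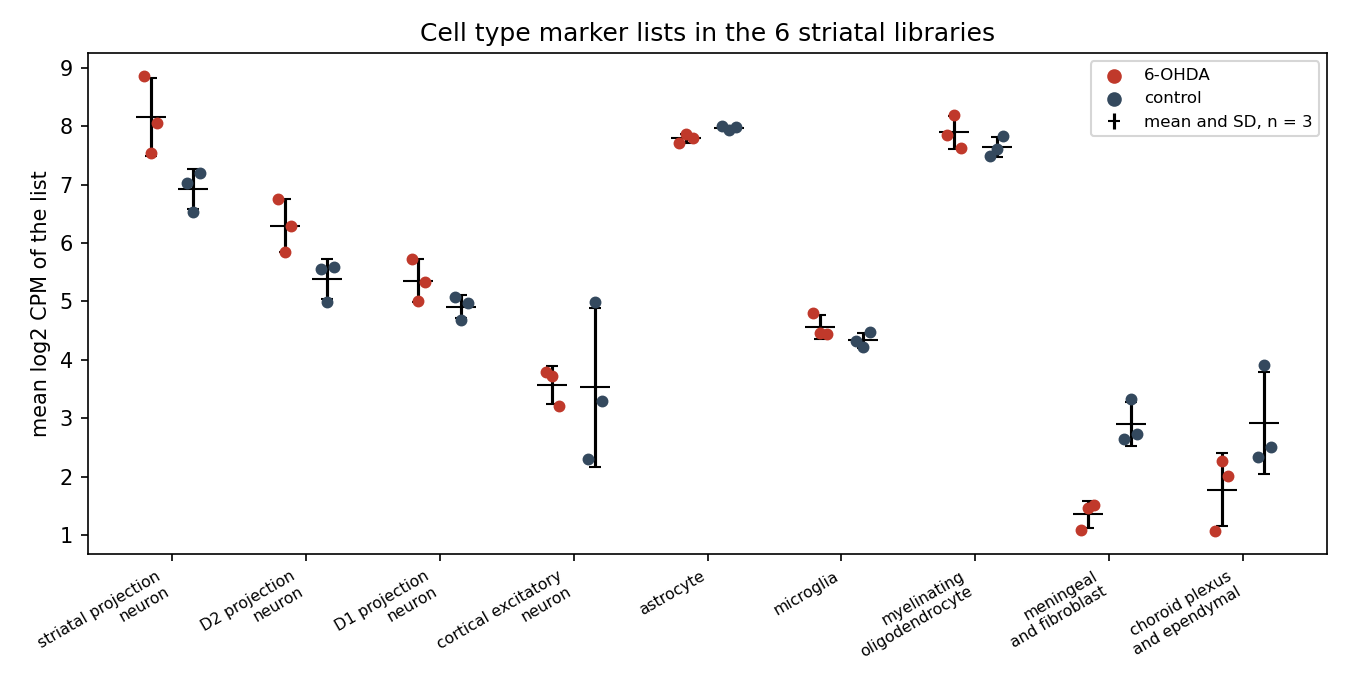
Mean log2 CPM of 9 marker lists in the 3 lesioned and 3 control striatal libraries (points, with mean and SD). Projection neuron markers lay at 7.55 to 8.86 in lesioned and 6.54 to 7.20 in control libraries, and meningeal and fibroblast markers at 1.09 to 1.52 and 2.65 to 3.33.

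Meningeal and fibroblast markers fell in lesioned striatum. Of 18 members 16 fell by either adjustment, with a median log2 fold change of -1.52 (adjusted p = 5.09e-19; adjusted p = 0.496 with an estimated correlation; adjusted p = 0.0016 by fry). The anion transporter gene Slc22a6 fell 7.63-fold, from 4.74 ± 0.94 to 0.61 ± 0.08 CPM (-2.93, SE 0.27, adjusted p = 4.86e-04), the retinoic acid synthesis gene Aldh1a2 from 5.46 ± 0.64 to 1.35 ± 0.46 (-2.01, SE 0.22), Ogn from 7.07 ± 1.80 to 1.78 ± 0.18 (-1.98, SE 0.21) and fibronectin, Fn1, from 69.1 ± 2.51 to 40.8 ± 4.42 (-0.76, SE 0.08). Of 16 choroid plexus and ependymal markers 1 fell, Ttr. The count was 5 when adjusted over the list alone (median -0.48, mean -1.53, adjusted p = 0.0041; adjusted p = 0.528 with an estimated correlation). In these libraries the projection neuron markers had the opposite direction, and the control library with the number 2 held the highest means of cortical, meningeal and choroid plexus markers. Without it the meningeal median was -1.33 with 11 members called, and without lesioned library 1 as well it was -1.16 with 10 called. The choroid plexus list did not pass without lesioned library 1 (median -0.33, adjusted p = 0.0768) or without both (median -0.15, adjusted p = 0.416), and its median was -0.97 without lesioned library 2.

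Glial lists moved by less. Of 20 microglia markers 2 rose, the receptor gene Csf1r (0.43, SE 0.10) and Fcrls (0.40, SE 0.11). The count was 5 when adjusted over the list alone (median 0.25, adjusted p = 0.0019; adjusted p = 0.553 with an estimated correlation). The microglia list did not pass without lesioned library 1 (median 0.13, adjusted p = 0.0887), where Csf1r was at 0.28. With both libraries in doubt left out, its median was 0.08 with 0 called. Of 25 myelinating oligodendrocyte markers 2 rose, transferrin, Trf (1.17, SE 0.16, adjusted p = 0.0036), and Hapln2 (0.89, SE 0.15). The counts were 4 higher and 1 lower when adjusted over the list alone (median 0.27, adjusted p = 0.0046; adjusted p = 0.647 with an estimated correlation). This list did not pass without lesioned library 2 (median 0.08, adjusted p = 0.398) or control library 1 (median 0.21, adjusted p = 0.0939), and its median was 0.42 without lesioned library 3. Of 17 astrocyte markers 4 fell, including Fgfr3 (-0.40, SE 0.08) and the gap junction gene Gjb6 (-0.51, SE 0.12), and 1 rose, Slc4a4 (0.44, SE 0.09); when adjusted over the list alone 10 fell and 1 rose (median -0.21, adjusted p = 0.0044; adjusted p = 0.496 with an estimated correlation). The astrocyte median was -0.13 without control library 1, and without both libraries in doubt Gjb6 was at -0.33 and Slc4a4 at 0.26. Of 15 reactive astrocyte genes 5 fell, including ceruloplasmin, Cp (-0.65, SE 0.12), and the heat shock gene Hspb1 (-1.89, SE 0.43). The counts were 6 lower and 1 higher when adjusted over the list alone (median -0.35, adjusted p = 6.30e-04; adjusted p = 0.496 with an estimated correlation). Without control library 2 the median was -0.16 with 1 called and Hspb1 was at -1.12 (adjusted p = 0.0509). With lesioned library 1 left out as well, the list did not pass (median -0.14, adjusted p = 0.106). The median was -0.56 without lesioned library 2 and -0.58 without control library 1. Of 17 oligodendrocyte precursor and committed cell markers 2 fell, Olig2 (-0.35, SE 0.10) and Itpr2 (-0.30, SE 0.08). The count was 5 when adjusted over the list alone (median -0.26, adjusted p = 0.0038; adjusted p = 0.528 with an estimated correlation). This list did not pass without lesioned library 3 (adjusted p = 0.0605), and its median was -0.17 without control library 3. Of 20 endothelial and mural cell markers 3 fell, including Cldn5 (-0.52, SE 0.11). The count was 4 when adjusted over the list alone (median -0.09), without the list passing (adjusted p = 0.0956). It passed without lesioned library 3 (median -0.16, adjusted p = 0.0492), control library 2 (median -0.14, adjusted p = 0.0265) or both libraries in doubt (median -0.15, adjusted p = 0.0146), and its median was -0.03 without lesioned library 2 and -0.02 without control library 3.

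Circadian clock genes were higher in lesioned striatum. Of 18 members 9 rose, and 12 rose when adjusted over the list alone (median 0.42, adjusted p = 1.07e-06; adjusted p = 0.496 with an estimated correlation). Per1, on chromosome 11 at 69095217 to 69109960, rose from 84.3 ± 3.14 to 154.3 ± 47.9 CPM (0.87, SE 0.19, adjusted p = 0.0253), and Ciart (1.01, SE 0.22), Hlf (0.78, SE 0.18) and Per3 (0.46, SE 0.10) rose too. Without both libraries in doubt the median was 0.22, Per1 was at 0.58, Ciart at 0.60 (adjusted p = 0.0582) and Hlf at 0.39, and Hlf was at 0.44 without lesioned library 1. In prefrontal cortex the same list was higher by a median of 0.09 (adjusted p = 0.0137; adjusted p = 0.752 with an estimated correlation) with 0 of 18 called and 2 when adjusted over the list alone, and it did not pass without control library 3 (adjusted p = 0.0539). Of 17 glucocorticoid-responsive genes 5 rose in striatum, among them the kinase gene Sgk1 (1.30, SE 0.18, adjusted p = 0.0037), Klf9 (0.73, SE 0.14) and Tsc22d3 (0.54, SE 0.11), and 1 fell, Sult1a1 (-0.59, SE 0.09); when adjusted over the list alone 7 rose and 1 fell (median 0.15, adjusted p = 0.0280; adjusted p = 0.496 with an estimated correlation). This list did not pass without lesioned library 2 (adjusted p = 0.115), control library 1 (median 0.07, adjusted p = 0.134) or control library 3 (median 0.08, adjusted p = 0.0697), and its median was 0.28 without control library 2 and 0.28 without both in doubt. Of 24 immediate early genes 3 rose, Nr4a1 (1.08, SE 0.28), Egr1 (0.96, SE 0.23) and Egr4 (0.95, SE 0.21), and 1 fell, Jun (-0.88, SE 0.24), against 5 and 1 when adjusted over the list alone (median 0.33, adjusted p = 0.0363; adjusted p = 0.647 with an estimated correlation). Immediate early genes did not pass without lesioned library 1 (median 0.15, adjusted p = 0.103), with Egr1 at 0.58 (adjusted p = 0.0630) and Egr4 at 0.60. They did not pass without control library 1 either (median 0.16, adjusted p = 0.708), and without control library 2 the median was 0.49 and Jun was at -0.43 (adjusted p = 0.0621). Of 22 heat shock and unfolded protein genes 4 fell, including Atf4 (-0.37, SE 0.10) and Pdia4 (-0.30, SE 0.07). The count was 8 when adjusted over the list alone (median -0.20, adjusted p = 7.35e-06; adjusted p = 0.496 with an estimated correlation). Atf4 was at -0.23 without both libraries in doubt (adjusted p = 0.0742). In the lesioned striatal libraries the projection neuron markers had a mean of 8.15 ± 0.66 log2 CPM, against 6.92 ± 0.34 in controls.

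Of 29 sodium and calcium channels 4 rose in striatum, Scn4b, Cacna2d3 (0.83, SE 0.20), Cacna1i (0.68, SE 0.16) and Hcn2 (0.33, SE 0.09). The count was 8 when adjusted over the list alone (median 0.26, adjusted p = 0.0041; adjusted p = 0.528 with an estimated correlation). The channel list did not pass without lesioned library 1 (median 0.08, adjusted p = 0.0546), with Scn4b at 1.24, Cacna2d3 at 0.46 and Cacna1i at 0.40. With control library 2 left out as well, its median was 0.13 and Hcn2 was at 0.20 (adjusted p = 0.134). Of 26 attention-deficit/hyperactivity disorder genes 3 rose by either adjustment, Foxp1, the serotonin receptor gene Htr1b (1.11, SE 0.22) and Baiap2 (0.72, SE 0.19), with a list median of 0.18 (adjusted p = 0.0306; adjusted p = 0.496 with an estimated correlation). The disorder list did not pass without lesioned library 1 (median 0.10, adjusted p = 0.0515; Baiap2 0.38, adjusted p = 0.0811), control library 1 (adjusted p = 0.125), control library 2 (adjusted p = 0.0586) or both in doubt (median 0.11, adjusted p = 0.0503; Htr1b 0.61, Foxp1 0.81). Scn4b and Foxp1 are also on the list of striatal projection neuron markers, whose median was 1.29 in the same contrast. Nuclear-encoded respiratory chain genes had a median of -0.10 with 0 of 61 called by either adjustment (adjusted p = 1.74e-04; adjusted p = 0.528 with an estimated correlation); Atp5g1 was at -0.16 (SE 0.06), and the median was -0.06 without control library 2. Cytosolic ribosomal protein genes had a median of -0.04 with 0 of 78 called by either adjustment (adjusted p = 0.0464; adjusted p = 0.794 with an estimated correlation); Rplp0 was at -0.20 (SE 0.09). The ribosomal list did not pass without lesioned library 1 (median 0.002), lesioned library 3, control library 2 or control library 3 (adjusted p = 0.528, 0.0839, 0.417 and 0.170). Its median was -0.01 without control library 2, 0.02 without both in doubt, -0.07 without lesioned library 2 and -0.07 without control library 1, and Rplp0 was at -0.10 without control library 2. With the correction for GC content and transcript length, medians and quartiles were 0.26 (-0.01 to 0.33) before and 0.17 (-0.02 to 0.30) after for the channels (adjusted p = 0.104). The disorder genes had 0.18 (0.01 to 0.32) before and 0.12 (-0.02 to 0.29) after (adjusted p = 0.164) and the respiratory chain genes -0.10 (-0.14 to -0.06) before and -0.05 (-0.12 to -0.001) after (adjusted p = 0.971). Why these 3 calls ended was not tested. The ribosomal genes reversed to higher (-0.04 (-0.08 to -0.001) before and 0.01 (-0.04 to 0.05) after, adjusted p = 0.0089). Extracellular matrix genes passed with the correction, lower, and not before (-0.06 (-0.25 to 0.03) before and -0.10 (-0.31 to -0.05) after, adjusted p = 0.0039).

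Camera gave 18 lists in striatum, 10 higher and 8 lower, fry gave 11, and camera with an estimated correlation gave 0 (smallest adjusted p = 0.496; 1 list at an unadjusted p below 0.05). Of the 1040 genes, 1027 had lesioned libraries apart from the controls, against 25.7% of tested genes and 10% by chance. With the spread of the 6 striatal libraries alone, edgeR called 4 genes at an adjusted p below 0.05 (smallest adjusted p = 0.0427 for Slc22a6), DESeq2 529 and limma-voom 0 (2405 genes at an unadjusted p below 0.05), although 1031 of the 1040 had an unadjusted p below 0.05 in edgeR. Without lesioned library 1 and control library 2, which differ from their groups in marker means, the fit of the others called 577 genes, 431 of them among the 1040. Leaving out 1 library at a time gave 267 to 681 genes for 11 of the 12 libraries and 2098 without lesioned striatal library 2.

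Transcripts of dopamine neurons themselves were sparse in both regions, whose dopamine input comes from cell bodies in the midbrain. Tyrosine hydroxylase, Th, on chromosome 7 at 142892752 to 142931128, was at 11.3 ± 2.10 CPM in lesioned and 9.93 ± 2.67 in control striatum (0.19, SE 0.30, adjusted p = 0.730). It was at 2.67 ± 0.38 and 4.98 ± 2.79 in prefrontal cortex (-0.94, SE 0.36, adjusted p = 0.342). Without control prefrontal library 1, which holds 8.20 CPM, the prefrontal value of Th was -0.34 (SE 0.28). That library also held 795 counts of the olfactory bulb marker Cdhr1, against 44 and 53 in the other prefrontal controls. Without control striatal library 2 the striatal value of Th was -0.02. The vesicular transporter gene Slc18a2 was at 5.04 ± 3.66 and 6.76 ± 1.52 CPM in striatum (-0.41, SE 0.50, adjusted p = 0.635) and at 0.27 ± 0.04 and 0.37 ± 0.26 in prefrontal cortex. Its direction turned without lesioned striatal library 1 (0.07, SE 0.26) and, in prefrontal cortex, without control library 1 (0.20, SE 1.36). Ddc had log2 fold changes of -0.79 (SE 0.19, adjusted p = 0.139) in prefrontal cortex, where it fell in the fit of prefrontal libraries alone (adjusted p = 0.0063), and -0.45 (SE 0.17, adjusted p = 0.117) in striatum, there -0.28 without lesioned library 1. The transporter gene Slc6a3 did not pass the filter. The list of dopamine neuron and terminal genes had 0 of 9 members called in each region, with 1 lower in prefrontal cortex when adjusted over the list alone (median -0.27, adjusted p = 0.106; striatum -0.20, adjusted p = 0.525).

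The receptor genes Drd1 and Drd2 were close to the threshold in striatum without passing it. Drd2, on chromosome 9 at 49340627 to 49408177, was at 194.7 ± 85.7 CPM in lesioned and 66.3 ± 16.4 in control striatum (1.55, SE 0.44, adjusted p = 0.0524), and Drd1, on chromosome 13 at 54051183 to 54055705, at 210.3 ± 99.7 and 92.7 ± 24.2 (1.18, SE 0.35, adjusted p = 0.0601). With lesioned library 1 left out Drd1 was at 0.73, and without control library 2 as well Drd2 was at 0.96 and Drd1 at 0.53 (adjusted p = 0.139 and 0.251). Drd5 was at 5.01 ± 0.74 and 5.91 ± 1.04 CPM (-0.235, adjusted p = 0.477), at -0.12 without lesioned library 1, -0.09 without control library 2 and 0.025 without both. The D1 peptide genes Tac1 (0.47, SE 0.27, adjusted p = 0.287) and Pdyn (0.41, SE 0.18, adjusted p = 0.161) did not pass, and were 0.10 without lesioned library 1 and 0.25 without control library 2. Fos was at -0.27 (SE 0.23, adjusted p = 0.490), at -0.56 without control library 1 (adjusted p = 0.0354), at -0.17 without control library 2 and at -0.03 without control library 3. In prefrontal cortex Drd1 was at -0.28 (SE 0.39) and Drd2 at -0.87 (SE 0.57), with adjusted p of 0.872 and 0.652, and without control library 3 at 0.03 and -0.17. The plot of dopamine-system genes per library gives the single values.

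**Figure D2:**
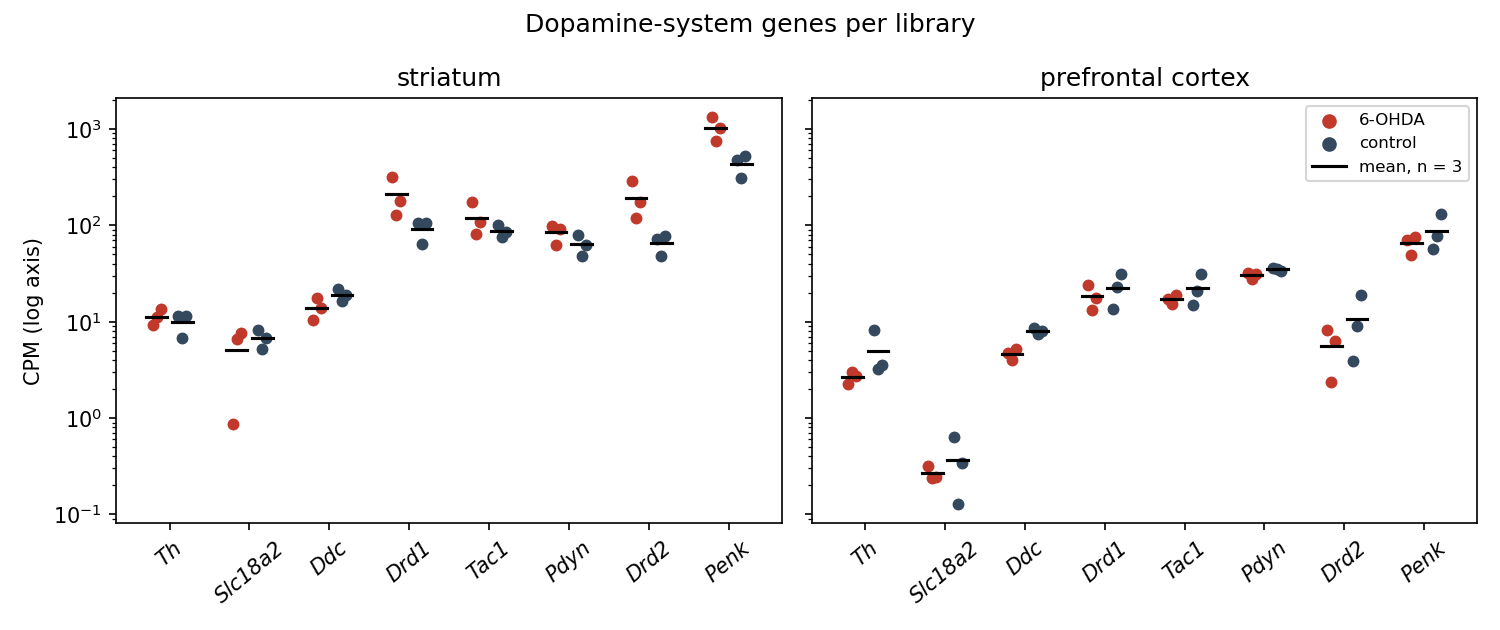
CPM on a log axis for 8 dopamine-system genes in the 3 lesioned and 3 control libraries of striatum (left) and prefrontal cortex (right), with group means as bars. Penk had a mean of 1035 CPM in lesioned and 434.8 in control striatum, while Th had means of 11.3 and 9.93.

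The lesion effects of the regions were compared gene by gene. All 30 genes called in prefrontal cortex had the same sign in striatum. Of the 11 that rose, 5 also rose in striatum (0.46 expected from independent lists, one-sided Fisher's exact p = 4.52e-05), including H1f2 and H1f4. Of the 19 that fell, 15 also fell there (0.57 expected, p = 4.02e-20 by the same exact test), including Cbs, Smox, Pdia4, Sult1a1 and the adhesion molecule gene Vcam1, which fell by 0.41 (SE 0.07) in prefrontal cortex and 0.59 (SE 0.07) in striatum. With the correction for GC content and transcript length, Pdia4, Sult1a1 and Vcam1 were not called in prefrontal cortex (adjusted p = 0.0628, 0.071 and 0.0739). Cbs and Smox kept their calls there. Over all genes the correlation of the log2 fold changes was r = 0.17 and rho = 0.264, across genes, which are not independent replicates, and 60.9% of genes had the same sign. The correlation was 0.102 without lesioned prefrontal library 1 and also without control prefrontal library 1, and 0.06 with no filter on low counts. No library is shared by the contrasts, and whether an animal gave both regions is not given in the sources used here. Both lists of calls come from 1 fit that shares the spread of each gene, and genes that move together are not independent. Fisher's test assumes independent lists and genes, so its p-values do not measure evidence for a shared response.

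**Figure D3:**
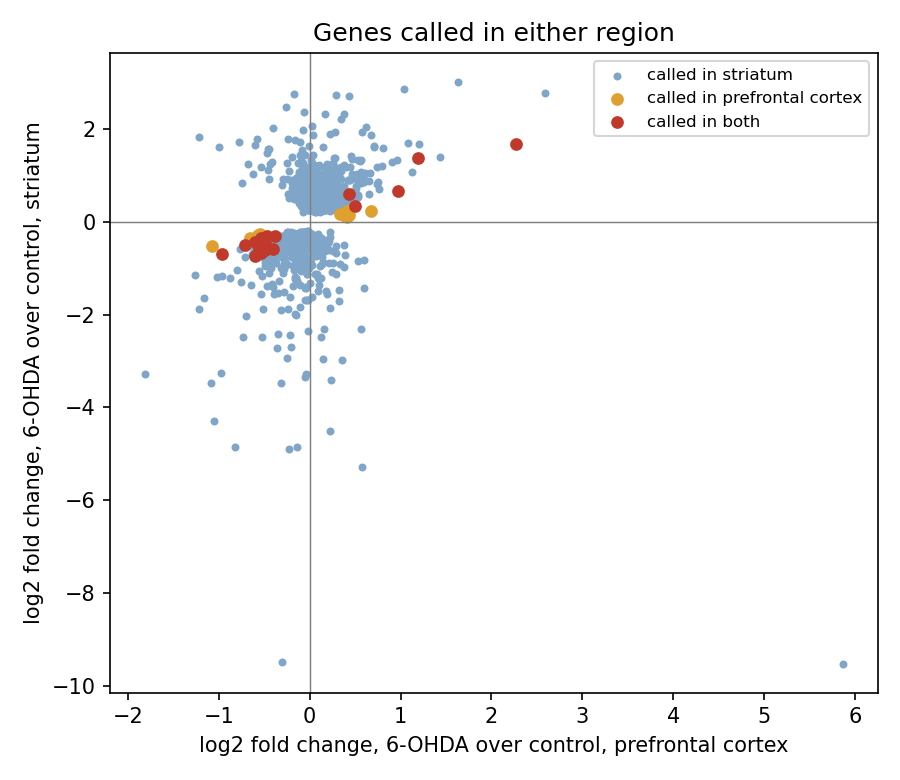
Log2 fold change after 6-OHDA in prefrontal cortex (x) and striatum (y) for each gene called in either region. The 20 genes called in both lie in the quadrants of equal sign, and 77.1% of the genes called in striatum had the same sign in prefrontal cortex.

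The fitted effect of the lesion differed between regions in 12 genes, 2 with a more positive value in striatum and 10 with a more negative one. Meningeal markers among them cannot tell a response to the lesion from a different extent of bordering tissue in the dissected striatum. The proteoglycan gene Fmod (difference of log2 fold changes -2.22, SE 0.24, adjusted p = 0.0125), Slc22a6 (-2.68, SE 0.34, adjusted p = 0.0161), Aldh1a2 (-1.87, SE 0.28, adjusted p = 0.0393) and Ogn (-1.82, SE 0.28, adjusted p = 0.0393) had more negative effects there, and the last 3 are meningeal markers on the fixed list. By camera 12 lists differed between regions, 7 upward in striatum and 5 downward, with 0 by an estimated correlation (smallest adjusted p = 0.519; 2 lists at an unadjusted p below 0.05) and 1 by fry. With the animal number shared by both regions as a block edgeR called 0 genes (1646 at an unadjusted p below 0.05), and with the replicate number as a block 6. The count of genes was 2 with limma-voom and 116 with DESeq2, and it was 172 without lesioned striatal library 2. Without control prefrontal library 1 or 2 edgeR called 0 genes, with 1422 and 1458 at an unadjusted p below 0.05 and 73 and 66 called by DESeq2.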

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

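The tests of transcript length and GC content on the genes that rose in prefrontal cortex and those of the 3 explanations for the striatal marker lists were chosen after the results were seen. Each difference in the next paragraph was picked out because the fitted effect of 6-OHDA differed between the regions by a test of that difference. For meningeal markers that test does not tell a response to the lesion from the extent of bordering tissue.

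The difference of the log2 fold changes, striatum minus prefrontal cortex, was -1.87 for Aldh1a2, -4.67 for Cdh1, -2.22 for Fmod, -4.72 for Mpzl2, -1.82 for Ogn, -5.85 for Prg4 and -2.68 for Slc22a6. Cdh1, Mpzl2 and Prg4 had 0 to 3 counts in each lesioned striatal library, so their fitted values are no bounds; that of Prg4 was -9.01 without lesioned striatal library 2. The median difference was 1.11 for dopamine receptors and signalling, 0.68 for D1 markers, 1.66 for D2 markers, 1.68 for striatal projection neuron markers, 0.29 for microglia markers, -0.46 for reactive astrocyte genes, 0.31 for myelinating oligodendrocyte markers, -1.23 for choroid plexus and ependymal markers, -1.63 for meningeal and fibroblast markers, 0.28 for clock genes, -0.10 for heat shock genes and -0.40 for interferon-response genes. These lists passed camera at an adjusted p of 0.0233 or less, with adjusted p of 0.519 or more under an estimated correlation.

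Without 1 library some of these list differences did not pass. Without lesioned striatal library 1 these were clock genes (0.12, adjusted p = 0.111) and heat shock genes (-0.04, 0.120). Heat shock genes did not pass without lesioned striatal library 3 (0.0733), control striatal library 3 (0.133) or control prefrontal library 1 or 3 (0.0632 and 0.0511) either. Myelinating oligodendrocyte markers did not without lesioned striatal library 2 (0.13, 0.352), control prefrontal library 3 (0.16, 0.125) or control striatal library 1 (0.0543). Interferon-response genes did not without control striatal library 2 (-0.18, 0.157) or control prefrontal library 1 (0.0524). Without control striatal library 2 the difference was -0.28 for reactive astrocyte genes and -0.56 for choroid plexus markers. Without both striatal libraries in doubt D1 markers (0.37, 0.0993), microglia (0.11, 0.0520), clock (0.09, 0.251), heat shock (-0.05, 0.0993) and interferon-response genes (-0.16, 0.351) did not pass. The differences were then 0.61 for dopamine receptors and signalling, 0.96 for projection neuron markers, -0.18 for reactive astrocyte genes and -0.30 for choroid plexus markers.

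Of 100 splits of the libraries within each region, 5 gave at least the 12 genes of the real one, and the highest other gave 922. These 5 are among the 11 splits that keep the lesioned striatal libraries apart from the controls, so they hold the striatal lesion effect. The split with 922 keeps the prefrontal groups and swaps the striatal ones. Its contrast is therefore the sum of the lesion effects of both regions with the sign turned, not their difference. The 89 splits that mix the striatal groups gave 0 genes each. The count of 5 therefore does not decide whether chance is excluded for the difference between regions. The 10 splits of 3 against 3 are too few for a share under 0.05. Only 1 split, the real one, reached the 30 genes in prefrontal cortex (highest other 0), the 803 in its libraries alone (0), the 1040 in striatum (3) and the 6243 between regions in controls (0). For lists, 1 split reached the 12 of prefrontal cortex (highest other 11) and 3 reached the 18 of striatum (highest other 19).

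Fold changes went the same way in both regions for 60.9% of genes, and long genes were among those that rose in prefrontal cortex. Across genes, the log2 fold change correlated with transcript length in both regions (rho = 0.176 in prefrontal cortex and 0.162 in striatum). A correction for GC content and transcript length brought these values to 0.011 and 0.009. It left the correlation between the regions at r = 0.159 against 0.17, which argues against such a bias as the whole cause of that correlation. The share of genes with the same sign and the rank correlation between the regions were not computed after the correction, so such a bias stays open for them. The 9 genes that rose and have an annotated length had a median log2 fold change of 0.345 after it and 0.427 before, and 7 of them lost their calls. The 4 with the longest transcripts lost them as the fold change shrank: Kmt2a went from 0.49 (SE 0.06) to 0.30 (SE 0.05), Kmt2c from 0.33 (SE 0.05) to 0.16 (SE 0.05), Mycbp2 from 0.39 (SE 0.06) to 0.21 (SE 0.05) and Vps13c from 0.41 (SE 0.07) to 0.28 (SE 0.07). Such a bias stays open for the rise of these 4. Elmsan1 (0.41 to 0.34, SE 0.07 for each), Trib1 (0.68 to 0.65, SE 0.11) and Utp14b (0.97 to 0.92, SE 0.17) moved less and ended at adjusted p of 0.0582 to 0.0726. Lgi4 (0.43, SE 0.06, to 0.41, SE 0.05) and Slc9a8 (0.43, SE 0.07, to 0.40, SE 0.06) kept their calls, at adjusted p of 0.0173 and 0.0499. Their fold changes moved by less than their SE, which argues against such a bias as the whole cause of these 2 rises. Trib1 and Utp14b also moved by less than their SE, so the threshold alone sets them apart from Slc9a8. A response to the lesion in both regions stays open and was not tested.

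In lesioned striatum projection neuron markers were higher and meningeal markers lower. Without the control library highest in cortical markers, a test that replaced 1 on the cortical list after its median of -0.44 was seen, the projection neuron median was 1.11 against 1.29, which argues against cortical tissue in controls as the whole cause. The medians of 6 other cell type lists spread over 1.80. This range holds the meningeal median, which was known when its limit was set, so it cannot decide about an even dilution of projection neurons. Outside the meningeal and choroid plexus lists, the oligodendrocyte and microglia medians were 0.27 and 0.25. The astrocyte and endothelial ones were -0.21 and -0.09. A different extent of bordering tissue could not be told apart from a response to the lesion: the meningeal median was -1.52 in striatum and -0.15 in prefrontal cortex, and the dissection of each group cannot be separated from its treatment. Without both libraries in doubt the medians were 0.70 and -1.16, with 4 and 10 members called.

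The clock list passed camera as higher in both regions, with 0 of 18 members called in prefrontal cortex and 9 in striatum. With an estimated correlation it passed in neither (adjusted p = 0.752 and 0.496), and in prefrontal cortex it did not pass without control library 3 (adjusted p = 0.0539). A different time of day at tissue collection predicts that the output arm and the opposite-phase arm move apart. In prefrontal cortex the medians were 0.17 and -0.15, so the arms moved apart, with 2 of 5 opposite-phase genes above 0. In striatum both medians were above 0, at 0.61 and 0.15, with 4 of 5 opposite-phase genes above 0. The SE of the mean of these 5 was 0.12. The median of 0.15 did not pass the bound set for a move in the same direction by more than that SE. Collection time therefore cannot be told apart from a response to the lesion.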

How the results depend on the processing

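The alternatives with a correction for GC content and transcript length, without both striatal libraries in doubt, with quality weights, with DESeq2 or limma-voom on the compared libraries, and with other treatments of the multiples of 11 were chosen after seeing the data, as were leaving out each library with DESeq2 and the list medians without each library of a region. The naming rule took 25, 104, 8 and 16 called genes for prefrontal cortex, striatum, the difference between regions and the regions in controls. In the fits that tested them, each kept its direction, and 0, 0, 0 and 15 were called in all of those fits. Not every fit tested each gene: 22 of the 25 were tested with the correction and 98 of the 104 with DESeq2 on the compared libraries. Directions of single genes were not tabled for leaving out each library with DESeq2 or with edgeR on 1 region.

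The count of 30 genes in prefrontal cortex became 191 with DESeq2, 803 with the compared libraries alone, 15 with the replicate number as a block, 145 with 1 surrogate variable, 56 at an adjusted p below 0.1, 508 without both striatal libraries in doubt, 16 with the correction for GC content and length, 709 with limma-voom with quality weights, 771 with the correction on the compared libraries, 843 with DESeq2 and 827 with limma-voom on the compared libraries. The count of 1040 in striatum became 1639 with DESeq2, 4 with the compared libraries alone, 590 with 1 surrogate variable, 2123 at an adjusted p below 0.1, 577 without both libraries in doubt, 1827 with quality weights, 10 with the correction on the compared libraries, 529 with DESeq2 and 0 with limma-voom on the compared libraries (2405 at an unadjusted p below 0.05). The spread explains part of this by construction: the compared libraries alone use a biological coefficient of variation of 5.8% in prefrontal cortex and 14.9% in striatum in place of 11.3%. For the other alternatives the cause was not tested. Keeping the multiples of 11 as deposited gave 25 and 709 genes, and dividing them by 11 gave 30 and 1030.

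The count of 12 genes that differed between regions became 116 with DESeq2, 2 with limma-voom, 6 with the replicate block, 0 with edgeR and the animal number as a block (1646 at an unadjusted p below 0.05), 21 with 1 surrogate variable, 20 at an adjusted p below 0.1, 101 without both libraries in doubt, 86 with quality weights and 5 with the multiples of 11 kept. Deviations from the group means correlated at -0.004 to 0.075 for libraries with the same number in the lesioned groups of both regions and at -0.004 to 0.092 in the control groups, against at most 0.053 and 0.028 for other numbers. Lesioned prefrontal and control striatal libraries, which cannot share an animal, gave 0.045 to 0.112 for the same number, so these values do not settle whether numbers mark animals.

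The correlation of 0.17 between the fold changes of the regions became 0.211 with limma-voom, 0.06 with no filter on low counts, 0.236 with the compared libraries alone, 0.21 with limma-voom and the animal number as a block, 0.121 with 1 surrogate variable, 0.24 without both libraries in doubt, 0.225 with quality weights, 0.223 with the correction on the compared libraries, and 0.233 with DESeq2 and 0.255 with limma-voom on these. The 12 lists of prefrontal cortex became 0 with an estimated correlation and 0 with fry, and the 18 of striatum 0 and 11; unadjusted, 2 and 6 lists passed in prefrontal cortex and 1 and 17 in striatum.

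Leaving out each library gave 0 to 100 genes in prefrontal cortex, 267 to 2098 in striatum, 0 to 172 for the difference between regions, 5082 to 7015 for the regions in controls, a correlation of 0.102 to 0.204, 10 to 16 lists in prefrontal cortex and 14 to 21 in striatum. The value of 0 in prefrontal cortex came without any 1 of its 6 libraries, with 1163 to 1391 genes at an unadjusted p below 0.05. With DESeq2 the ranges were 53 to 335, 698 to 2325 and 36 to 679, and with edgeR on 1 region 195 to 1010 in prefrontal cortex and 0 to 2 in striatum. RLE and upper-quartile factors, at least 1 CPM in 3 libraries and a minimum log2 fold change of 0.3 left each count within 1.5 times its value. Leaving out mitochondrial genes changed nothing, since they are listed at 0. Depth limits genes near the floor of 0.143 to 0.199 CPM.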

Other observations

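The test of the Drd2 to Drd1 ratio was chosen after the ratio was seen. In striatum 7 of 44 potassium channels rose, including Kcna4 (0.97, SE 0.16) and Kcnab1 (1.06, SE 0.24), and 1 fell, against 15 and 5 when adjusted over the list alone (median 0.14, adjusted p = 0.0815). This list passed without lesioned library 2 (adjusted p = 0.0464), and without lesioned library 1 its median was 0.07 and Kcnab1 was at 0.62. Of 42 axon guidance genes 5 rose and 3 fell, 6 and 7 when adjusted over the list alone, including the receptor genes Robo2 (0.89, SE 0.19) and Dcc (0.60, SE 0.12) and, lower, Epha3 (-0.98, SE 0.18; median -0.11, adjusted p = 0.377). Robo2 was at 0.55 without lesioned library 1 and control library 2. Of 22 glutamate receptors 3 rose, among them Grm3 (0.69, SE 0.14) and Grm5 (0.51, SE 0.12; median 0.18, adjusted p = 0.132). Without both libraries these were at 0.42 and 0.30 (adjusted p = 0.0726 for Grm5). Of 17 genes of GABA receptors and transport 2 rose, Gabrd (0.96, SE 0.24) and Gabra4 (0.73, SE 0.18; median -0.08, adjusted p = 0.682); without lesioned library 1 they were at 0.51 and 0.39. Of 22 monoamine genes 2 rose, Htr1b and Hrh3 (0.79, SE 0.21), and 1 fell, Htr1a (-0.97, SE 0.26; median -0.03, adjusted p = 0.924). Without lesioned library 1 Hrh3 was at 0.50 (adjusted p = 0.113), Htr1a at -0.64 and the opioid receptor gene Oprd1 at 0.41, and without control library 2 as well Htr1b was at 0.61. The opioid and cannabinoid genes Penk and Oprd1 (0.73, SE 0.18) rose among 13 members (adjusted p = 0.233). Of 20 neuropeptide genes 1 rose, Penk, and 2 fell, Cartpt (-1.17, SE 0.32) and Igf1 (-0.58, SE 0.15; adjusted p = 0.563), with Cartpt at -0.77 without both libraries.

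Of 25 synaptic vesicle genes 2 rose in striatum, including Sv2c (0.63, SE 0.16), and 1 fell, Syp (-0.33, SE 0.09; adjusted p = 0.831). Without lesioned library 1 and control library 2 they were at 0.38 (adjusted p = 0.0664) and -0.19 (adjusted p = 0.0707). Among cortical excitatory neuron markers Lmo3 rose (0.62, SE 0.17) and Cux2 fell (-0.46, SE 0.07); the median of 16 members was -0.44 and the mean -0.64, while camera pointed upward without passing (adjusted p = 0.626). Lmo3 was at 0.39 without lesioned library 1 (adjusted p = 0.141). Reln rose among 16 interneuron markers (0.79, SE 0.17; adjusted p = 0.749) and was at 0.50 without both libraries (adjusted p = 0.0555). Of 25 extracellular matrix genes 1 rose and 2 fell, Nid1 (-0.73, SE 0.10) and Col4a1 (-0.44, SE 0.08; adjusted p = 0.0815), and of 24 neurotrophic genes 2 fell, Igf1 and Igf2 (-2.48, SE 0.29; adjusted p = 0.198). Among 16 cytokine and inflammation genes Il33 rose (0.71, SE 0.15) and Vcam1 fell (adjusted p = 0.749). Interferon-response genes had a striatal median of -0.03 (adjusted p = 0.960).

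Among the lists with 0 called members in striatum were the postsynaptic scaffolds (median 0.09, adjusted p = 0.374), blood cell markers (-0.98, 0.144), olfactory bulb markers (-0.28, 0.175), thalamic and other subcortical markers (-0.47, 0.0634) and immature neuron and proliferation markers (-0.10, 0.342). The hypothalamic list, of whose 21 markers 10 were tested, had a median of -0.19 with 0 called. In prefrontal cortex Sult1a1 fell among 17 glucocorticoid-responsive genes (adjusted p = 0.281) and Vcam1 among 16 cytokine and inflammation genes (adjusted p = 0.701), and olfactory bulb markers had a median of -0.66 (adjusted p = 0.284), which turned to 0.33 without control library 1. It was -1.03 without lesioned library 2, -1.05 without control library 2 (adjusted p = 0.0358) and -1.03 without control library 3. Chrm4 rose in striatum among 16 acetylcholine genes (adjusted p = 0.840) and was at 0.64 without lesioned library 1.

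Drd2 counts per Drd1 count were 0.934 ± 0.039 (SD, n = 3) in lesioned and 0.718 ± 0.028 in control striatum, and Penk counts per Tac1 count 8.84 ± 1.07 and 4.98 ± 1.05 (exact permutation p = 0.1 for each, the smallest that 3 against 3 can give). A hypothesis is that the lesion may raise transcripts of the indirect pathway over those of the direct pathway. The mean of D2 minus D1 markers was higher by 0.469 in lesioned libraries. The exact permutation p of 0.1 is again the smallest possible, so this test cannot decide.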
